A study of Mus musculus with 10 samples.

How the data were processed

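The samples are 10 whole subcutaneous MC38 tumours, 5 of high and 5 of low tumour burden, profiled by RNA-seq. Per the labels' protocols, total RNA was extracted with a silica column kit and libraries were made with a SMARTer mRNA kit. Per the labels, the genome build was GRCm38, also called mm10. The aligner, the counting tool and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The table deposited by the authors gives estimated counts per gene and library, not scaled to depth. Of these values 86.4% were whole, within 1e-09, and the rest were rounded to whole numbers, a change of at most 0.5. Fractional values can arise where reads are divided among genes, so members of gene families with near-identical copies are treated as uncertain.

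The same deposited table holds the authors' own comparison: a log2 fold change, and a p-value and q-value that the column headers attribute to DESeq2, with no version. Its log2 values are positive where HTB is higher, tested on the reads of the same table, in 100% of the genes it calls. In the authors' deposited table, there are 2638 genes that have a q under 0.05, 1246 higher and 1392 lower in HTB. The table has 18223 genes, identified by symbol and NCBI gene ID. It lists genes of type mRNA only and no mitochondrially encoded genes, so the planned mitochondrial share and list were not analysed here. A line with no gene was left out, and 1 symbol that occurs on 2 lines, Plin2, was kept apart by gene ID. Of the IDs, 18101 (99.3%) matched the RefSeq gene table.

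Library totals ranged from 23070917 to 27185168 estimated reads. A floor of 3 reads was used where a group had 0, and it covers counting error only, since the reads carry no molecular identifiers. As a check of labels, the Y-linked genes Ddx3y and Eif2s3y had 1 and 27 reads over all 10 libraries. No 2 libraries of a group agreed within sampling noise, so each counted as 1 sample.

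The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors between 0.975 and 1.03, after the filterByExpr filter, on all 10 libraries with group as the only term. It tested 13470 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. CPM values used the TMM-scaled totals, and those of Igfbp2 the plain totals. Tests on simulated counts with the means and library sizes of this comparison, with 50 genes changed at each size among 13470, recovered 34% of genes changed 1.5-fold, 70% at 2-fold, 94% at 4-fold and 94% at 8-fold, and 3.95% of calls were false. The changed genes were drawn from those with a mean above 1 CPM, so these recovery rates do not cover genes of lower counts. A simulated list of 20 genes lowered 2-fold was found by camera and 0 of 27 unchanged lists were. The simulated genes varied independently of each other. This check therefore does not show how often camera calls unchanged lists whose genes are correlated.

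Before the data were examined, 30 gene lists were fixed for immune and stromal cell types, programmes of tumour growth, the genes of the series title and tissues next to a subcutaneous tumour. The sex-linked list served only the label check. The 28 lists with at least 3 tested genes were compared with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 28. Camera asks whether a list's genes change relative to the other genes. List means were means of log2(CPM + 1) over the tested members, compared by an exact permutation test. Many immune genes occur in several lists, and the macrophage, neutrophil and chemokine lists hold genes that other cells of a tumour also express.

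The genes named in the text were chosen by a rule fixed in advance: the 3 genes of the series title, the 8 largest positive and 8 largest negative log2 fold changes among genes that passed with a mean log2 CPM of at least 1, leaving out symbols of predicted genes (Gm plus digits, or ending in Rik), and the 3 members of smallest p in each list described. Some genes that this rule selects are not reported here. Other genes named were chosen after their values were seen: Cd68, Ccl17, Il1r2, Hif1a, Icam1, Osm, Bcl2l1 and Dnajb1 because they complete a count, and those of the closing section.

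The alternatives were DESeq2 size factors and upper-quartile factors in edgeR, the DESeq2 Wald test (DESeq2 1.42.0), limma voom with and without sample quality weights, no filter on low counts, a filter of at least 1 CPM in 5 libraries, other thresholds, the replicate number as a block, and leaving out each library in turn. Lists were repeated with an estimated correlation and with fry, and list means with a pseudocount of 0.1 and as z-scores. Added after seeing the data were thinning all libraries to the smallest total and leaving out HTB replicate 2 and LTB replicate 1 together. The ratio for Igfbp2 without LTB replicate 1, and the relation of Stat3 with Cd274 without each library, were also added then. The other scalings moved the median log2 fold change of all genes by less than 0.1. Figures and permutation tests were made in Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.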

Results

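RNA was sequenced from subcutaneous tumours grown from MC38, a mouse colon adenocarcinoma cell line that is widely used because it forms tumours in immunocompetent mice. The 10 libraries fall into 2 groups of 5: high tumour burden (HTB) and low tumour burden (LTB). The treatment labels give 2000000 for HTB and 500000 for LTB, both over 14 days, which is read here as the number of MC38 cells injected and the days of growth. No label records a measured tumour size. The tissue was whole tumour, so each library mixes RNA of tumour cells, infiltrating immune cells and stroma. The deposited table held 18223 protein-coding genes, and the libraries summed to between 24884292 and 27185168 estimated reads in HTB and between 23070917 and 26880191 in LTB. The labels do not say that each library came from a different animal, so every p-value below measures the spread between these libraries.

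The first question concerned the 3 genes named in the series title: Igfbp2, which encodes a binding protein for insulin-like growth factors, Stat3, a transcription factor activated by cytokines, and Cd274, which encodes the checkpoint ligand PD-L1. All 3 were lower in HTB. Cd274 fell from 76.7 ± 46.7 CPM (SD, n = 5) in LTB to 17.1 ± 3.79 CPM in HTB (n = 5), a log2 fold change of -2.16 ± 0.34 (SE; adjusted p = 0.0044, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Every HTB library, at 13.1 to 22.7 CPM, lay below every LTB library, at 42.3 to 159 CPM, and the highest LTB value belonged to replicate 1. Stat3 fell from 132 ± 13.5 to 100 ± 12.6 CPM, a log2 fold change of -0.40 ± 0.10 (adjusted p = 0.0257).

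Igfbp2 was near the detection limit in whole tumours. It had 0 reads in each of the 5 HTB libraries (132838352 reads together) and 25 reads in the LTB libraries (12, 2, 1, 5 and 5), or 0.194 ± 0.159 CPM (SD, n = 5). Pooled over the group this is 0.199 CPM. Set against a floor of 3 reads over the HTB group, 0.0226 CPM, the pooled LTB value was 8.8-fold higher. This ratio allows for counting error in HTB only. It leaves out the counting error of the 25 LTB reads and the spread between libraries, so the true ratio can be smaller. LTB replicate 1 holds 12 of the 25 reads, and without it the ratio is 5.8-fold. Igfbp2 was too low to enter the main edgeR test. With the filter on low counts removed, edgeR's adjusted p was 0.0351. DESeq2 gave an unadjusted p of 0.0013 and no adjusted value, and the authors' deposited table lists a q of 0.0135. In GRCm38 the deposited table places Igfbp2 (NCBI gene 16008) on chromosome 1 from 72824480 to 72852474 on the plus strand, Stat3 (20848) on chromosome 11 from 100886806 to 100939579 on the minus strand, and Cd274 (60533) on chromosome 19 from 29366576 to 29388095 on the plus strand. These spans cover whole genes, exons and introns together.

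**Figure D1:**
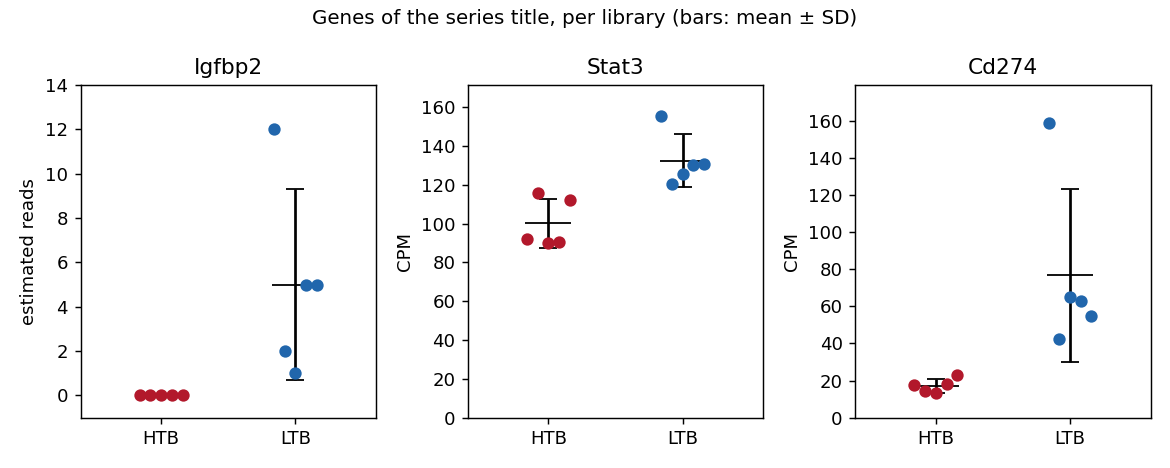
Igfbp2 in estimated reads and Stat3 and Cd274 in CPM (reads scaled to the library total), 1 point per library in the 5 HTB and 5 LTB tumours, with bars for the mean and SD. Igfbp2 had 0 reads in every HTB library and 1 to 12 in LTB, and no HTB library reached the lowest LTB value of Stat3 or Cd274.

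Across the transcriptome, more genes fell than rose with high burden. Of 13470 genes tested, 1011 were lower and 526 higher in HTB. At a change of at least 2-fold the imbalance was larger, with 546 genes lower and 63 higher. Leaving out HTB replicate 2, a library rich in muscle and fat transcripts, raised the count to 3040 (1324 higher and 1716 lower), and 1525 of the 1537 genes passed in both fits. The count fell to 739 without HTB replicate 3, 743 without HTB replicate 4, 933 without HTB replicate 5 and 940 without LTB replicate 3.

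The genes with the largest falls included genes of myeloid and mast cells. Mcpt2 (NCBI gene 17225), a mast cell protease, changed by -5.44 ± 0.97 on the log2 scale (SE; adjusted p = 0.0078). Its size is uncertain, since Mcpt2 had 0.437 CPM in HTB replicate 1, 0.037 in HTB replicate 5 and 0 in the other 3 HTB libraries, and without HTB replicate 1 it changed by -8.27 (adjusted p = 0.0015). Clec7a (56644), the beta-glucan receptor dectin-1 of macrophages and dendritic cells, fell from 87.9 ± 36.4 to 6.69 ± 1.48 CPM (SD, n = 5 each; log2 fold change -3.71 ± 0.34, adjusted p = 5.92e-04). Arg1 (11846), the arginase of alternatively activated macrophages, fell from 212 ± 166 to 17.0 ± 9.18 CPM (log2 fold change -3.64 ± 0.64, adjusted p = 0.0071). The coagulation factor genes F7 (14068) and F10 (14058) changed by -3.65 ± 0.67 and -3.57 ± 0.68, with adjusted p of 0.009 and 0.0097, F10 by -4.42 without HTB replicate 4. Tarm1 (245126), a receptor of myeloid cells, changed by -3.57 ± 0.65 (adjusted p = 0.0085), or -4.16 without HTB replicate 4. Ubd (24108), an interferon-gamma-inducible ubiquitin-like protein, changed by -3.51 ± 0.60 (adjusted p = 0.0065), or -4.21 without HTB replicate 2. Prl2c3 (18812) changed by -3.84 ± 0.54 (adjusted p = 0.0029), but it has near-identical copies in the prolactin family among which reads could be split, so its value is uncertain.

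The largest rises included 3 skeletal muscle genes and 3 genes expressed by subsets of tissue macrophages or lymphatic endothelium. The muscle genes Acta1 (NCBI gene 11459), Atp2a1 (11937) and Tnnt3 (21957) rose by 10.98 ± 2.94, 9.02 ± 2.60 and 7.28 ± 2.00 (log2, SE), with adjusted p of 0.0373, 0.0484 and 0.0407. Acta1 stood at 4062 CPM in HTB replicate 2, at 22.1 CPM in HTB replicate 3, at 0.474 to 3.04 CPM in the other HTB libraries and at 0.089 to 1.10 CPM in LTB. Without HTB replicate 2 the changes were 4.07 ± 1.09 (adjusted p = 0.0256), 1.42 ± 0.46 (adjusted p = 0.0509, no longer passing) and 1.72 ± 0.31 (adjusted p = 0.0056). The Acta1 value of that fit leans on HTB replicate 3. Tnnt3 was higher in every HTB library, at 4.63 CPM or more, than in any LTB library, at 3.07 CPM or less. Without LTB replicate 1, Acta1 stood at 11.85 (adjusted p = 0.0743). Lyve1 (114332), a hyaluronan receptor of lymphatic vessels and perivascular macrophages, rose from 1.22 ± 0.84 to 9.38 ± 7.37 CPM (SD, n = 5 each; log2 fold change 2.94 ± 0.78, adjusted p = 0.0353). Cd163 (93671), the haemoglobin scavenger receptor of macrophages, rose by 2.62 ± 0.67 (adjusted p = 0.0322), and the transporter gene Slco2b1 (101488) by 2.50 ± 0.56 (adjusted p = 0.0194). Ablim3 (319713) and Abca8a (217258) rose by 3.33 ± 0.82 (adjusted p = 0.0276) and 3.32 ± 0.87 (adjusted p = 0.0353). Without HTB replicate 2, Lyve1, Cd163, Slco2b1, Ablim3 and Abca8a still passed, with log2 changes of 2.56, 1.99, 1.73, 1.78 and 1.95. Not every HTB library was raised. Lyve1 in HTB replicates 1 and 5 (1.57 and 2.13 CPM) lay inside the LTB range of 0.195 to 2.31 CPM. Cd163 in HTB replicate 5 (1.06 CPM) and Abca8a in HTB replicate 1 (0.911 CPM) lay below the highest LTB values, 1.34 and 1.37 CPM. Slco2b1 and Ablim3 did not overlap between the groups.

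**Figure D2:**
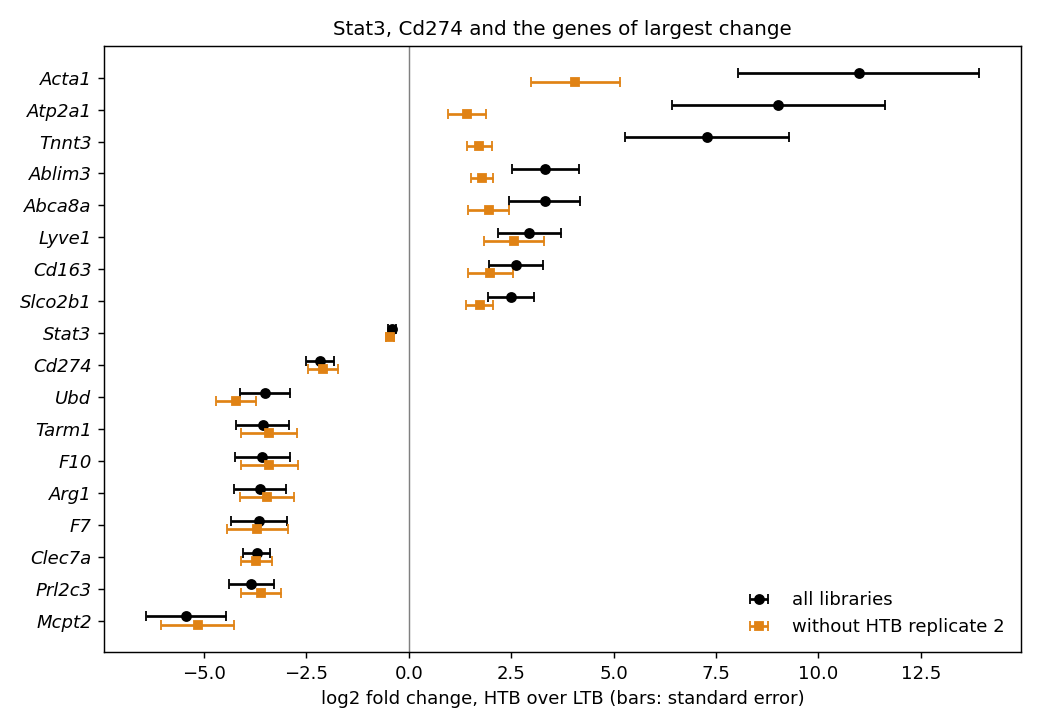
Log2 fold change, HTB over LTB, of Stat3, Cd274 and the 16 genes of largest change, with standard errors. Black circles use all 10 libraries and orange squares leave out HTB replicate 2, which moved Acta1 from 10.98 to 4.07 and left Clec7a at -3.72.

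Gene lists fixed before the data were examined were then compared between the groups. Antigen presentation genes fell together: all 19 of 19 tested members of that list were lower in HTB, over all genes and adjusted over the list alone. They include components of the class II loading machinery, with H2-DMa at -1.90 ± 0.16 (log2, SE; 16.0 ± 2.58 against 59.8 ± 12.4 CPM, SD, n = 5 each; adjusted p = 5.92e-04) and H2-DMb1 at -1.22 ± 0.09. The peptide transporter gene Tap1, which serves class I loading, changed by -1.57 ± 0.13. The list's camera test gave adjusted p = 3.78e-23 with the preset correlation and adjusted p = 0.145 with an estimated correlation.

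Interferon-induced genes fell in 21 of 33 tested members, and 25 adjusted over the list alone, with none higher in either count. The GTPase gene Gbp2 dropped from 859 ± 298 to 157 ± 30.2 CPM (SD, n = 5 each), a log2 fold change of -2.45 ± 0.23 (adjusted p = 5.92e-04). The transcription factor gene Irf1 changed by -1.40 ± 0.14. Camera gave adjusted p = 1.37e-20, and adjusted p = 0.175 with an estimated correlation. Of 26 chemokine and chemokine receptor genes, 15 fell (16 adjusted over the list alone) and 0 rose, among them Cxcl9 (-2.42 ± 0.37), which draws T cells, Ccl22 (-2.43 ± 0.27) and Cxcl16 (-1.44 ± 0.22). This list had adjusted p = 2.6e-09 by camera and adjusted p = 0.145 with an estimated correlation.

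Lymphocyte genes were lower in HTB across several lists. Of 17 T cell genes, 12 fell (16 adjusted over the list alone), including the kinase gene Lck (-1.68 ± 0.34) and the interleukin-7 receptor gene Il7r (-3.24 ± 0.52). Il7r had 51.8 CPM in LTB replicate 1 and 9.18 to 17.2 in the other LTB libraries, and without replicate 1 it changed by -2.57 (adjusted p = 0.0019). Camera gave adjusted p = 8.24e-10, and adjusted p = 0.179 with an estimated correlation. Of 17 genes of cytotoxic T cells and natural killer cells, 12 fell (17 adjusted over the list alone). Ifng, which encodes interferon gamma, fell from 5.44 ± 4.83 to 0.763 ± 0.265 CPM (SD, n = 5 each; log2 fold change -2.83 ± 0.52, adjusted p = 0.0089). LTB replicate 1 had 14.0 CPM of Ifng and the other LTB libraries 2.40 to 4.45, and without replicate 1 the log2 fold change was -2.11 (adjusted p = 0.0039). Xcl1 and Nkg7 changed by -2.39 ± 0.27 and -1.84 ± 0.34. This list had adjusted p = 2.18e-10 by camera and adjusted p = 0.175 with an estimated correlation.

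Regulatory T cell genes fell in 9 of 10 members (10 adjusted over the list alone), with Foxp3, the lineage transcription factor, at -2.57 ± 0.39 and Ccr8 and Tnfrsf4 at -3.66 ± 0.37 and -1.44 ± 0.22. Ccr8 was near the detection limit, at 0.036 to 0.073 CPM in HTB and 0.428 to 0.909 CPM in LTB, so the size of its fall is uncertain. For the list, camera gave adjusted p = 1.25e-08, and adjusted p = 0.145 with an estimated correlation. Of 19 checkpoint genes, 10 fell (16 adjusted over the list alone), among them Pdcd1lg2, which encodes PD-L2 (-3.48 ± 0.50), the tryptophan-degrading enzyme gene Ido1 (-4.53 ± 0.70) and Cd274. Pdcd1lg2 changed by -2.82 without LTB replicate 5, and Ido1 by -5.24 without HTB replicate 2. Ido1 was near the detection limit in HTB, at 0 to 0.373 CPM, so the size of its fall is uncertain. The checkpoint list had adjusted p = 6.71e-09, and adjusted p = 0.145 with an estimated correlation. Among 7 B and plasma cell genes 1 fell, Cd22 (-0.80 ± 0.20, adjusted p = 0.0316), and the count was also 1 adjusted over the list alone. Pax5 and Cd79b stood at -0.96 ± 0.34 (adjusted p = 0.0943) and -1.10 ± 0.44 (adjusted p = 0.129), and the list did not pass camera (adjusted p = 0.0597). It passed, lower in HTB, with the replicate number as a block (adjusted p = 0.0314), without LTB replicate 5 (adjusted p = 0.0399), with no filter on low counts (adjusted p = 0.004, 14 members) and by fry (adjusted p = 0.0023). Its value was adjusted p = 0.179 with an estimated correlation. With HTB replicate 2 left out, 3 of the 7 fell and 1 rose. LTB replicate 1 had the highest mean of the T cell list, 4.25 on the log2(CPM + 1) scale, where the other LTB libraries lay at 2.56 to 3.39 and HTB at 1.61 to 2.45.

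Macrophage genes went both ways. Of 20 general macrophage markers, Itgam, Msr1, Lyz2 and Cd68 fell, Cd163 rose, and 15 did not pass; adjusted over the list alone, 8 fell and 1 rose. Itgam, the integrin CD11b, changed by -1.23 ± 0.21, the scavenger receptor gene Msr1 by -1.28 ± 0.23 and the lysozyme gene Lyz2 by -1.15 ± 0.23. Cd68 changed by -0.64 ± 0.19, with an adjusted p of 0.0496 that became 0.0519 without HTB replicate 2. Camera gave the list adjusted p = 0.0026, lower in HTB, and adjusted p = 0.477 with an estimated correlation. Among 16 genes of alternatively activated macrophages 5 fell (Clec7a, Ccl22, Pdcd1lg2, Arg1 and Ccl17) and 1 rose (Cd163), or 7 and 1 adjusted over the list alone, with adjusted p = 8.6e-05 by camera and adjusted p = 0.183 with an estimated correlation. In the fit without HTB replicate 2, 8 of these 16 fell and 1 rose.

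Inflammatory macrophage genes fell in 9 of 16 members (13 adjusted over the list alone) and rose in 0. Nos2, the inducible nitric oxide synthase, fell from 42.8 ± 23.3 to 4.11 ± 2.66 CPM (SD, n = 5 each; log2 fold change -3.38 ± 0.49, adjusted p = 0.0033), and the costimulatory ligand gene Cd80 changed by -1.77 ± 0.30. The list had adjusted p = 4.27e-09 by camera and adjusted p = 0.179 with an estimated correlation. Of 15 dendritic cell genes, 6 fell (7 adjusted over the list alone), including Itgax (-2.81 ± 0.37), the migration receptor gene Ccr7 (-1.79 ± 0.25) and Irf8 (-1.33 ± 0.22), with adjusted p = 1.05e-04 by camera and adjusted p = 0.194 with an estimated correlation. Of 12 neutrophil genes, 4 fell in both counts: Trem1 (-2.40 ± 0.38), Acod1 (-3.16 ± 0.72), Clec4d (-3.03 ± 0.71) and Il1r2 (-2.47), with adjusted p = 0.0057 by camera and adjusted p = 0.473 with an estimated correlation. Acod1, Clec4d and Trem1 are also made by activated macrophages. LTB replicate 1 had 127 CPM of Acod1 (other LTB libraries 15.4 to 26.2) and 126 CPM of Clec4d (others 9.48 to 22.9). Without it Acod1 changed by -2.16 (adjusted p = 0.0255) and Clec4d by -1.81 (adjusted p = 0.0109), while without HTB replicate 4 Acod1 changed by -3.87. LTB replicate 1 also stood at 4.39 on the neutrophil list mean against 1.87 to 2.50 in the other LTB libraries. Without LTB replicate 1 and HTB replicate 2 the list's camera value was 0.0805.

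**Figure D3:**
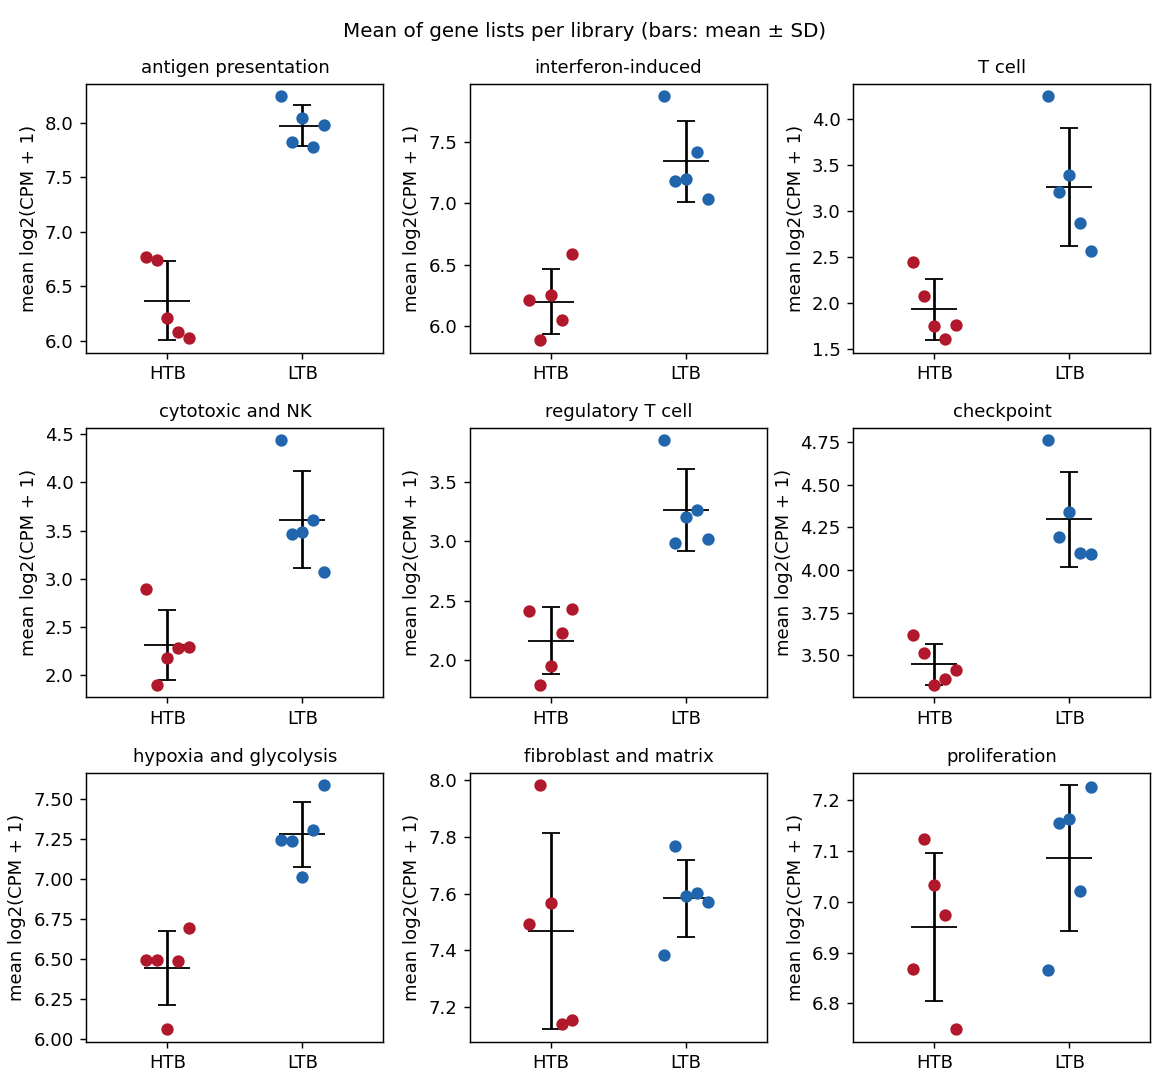
Mean log2(CPM + 1) of the tested members of 9 gene lists, 1 point per library, with bars for the mean and SD of the 5 HTB and 5 LTB libraries; each panel has its own axis, which does not start at 0. The antigen presentation list stood at 6.37 ± 0.36 in HTB and 7.98 ± 0.19 in LTB, while the fibroblast and proliferation panels overlap.

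Hypoxia and glycolysis genes were lower in HTB. Of 27 members, 17 fell (18 adjusted over the list alone) and 0 rose, among them the glycolytic enzyme genes Pfkp (-0.93 ± 0.09; 63.0 ± 7.16 against 120 ± 11.1 CPM, SD, n = 5 each; adjusted p = 5.92e-04) and Pgam1 (-0.75 ± 0.10). The collagen prolyl hydroxylase gene P4ha2 changed by -1.40 ± 0.17. Camera gave adjusted p = 3.75e-13, and adjusted p = 0.175 with an estimated correlation. The list of STAT3 and its targets and regulators held 7 genes that fell among 25 (9 adjusted over the list alone): Pim1 (-1.03 ± 0.20), Vegfa (-0.66 ± 0.14), Stat3, Hif1a, Icam1, Osm and Bcl2l1. It had adjusted p = 1.91e-04 by camera and adjusted p = 0.244 with an estimated correlation.

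Of 15 tested genes of the insulin-like growth factor axis, 1 rose, the receptor substrate gene Irs1 (0.41 ± 0.10, adjusted p = 0.0239), and 4 rose adjusted over the list alone. Igfbp4 stood at 0.23 ± 0.07 (adjusted p = 0.0613) and Igf2 at 2.80 ± 0.87 (adjusted p = 0.0629). Igf2 had 14.2 CPM in HTB replicate 2 and 0.583 to 2.64 CPM in the other HTB libraries, and without replicate 2 it stood at 1.23 (adjusted p = 0.0749). Camera placed this list higher in HTB with adjusted p = 0.0392, and adjusted p = 0.179 with an estimated correlation. Without HTB replicate 2, whose list mean of 6.91 stood above the 6.21 to 6.35 of the other HTB libraries, the preset value became 0.0784. The call was also lost without LTB replicate 1 (adjusted p = 0.0666) and with no filter on low counts (adjusted p = 0.0862).

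Proliferation genes moved little. Of 31 members, E2f1 (-0.34 ± 0.06) and Pcna (-0.36 ± 0.07) fell in both counts, and Rrm2 stood at -0.47 ± 0.15 (adjusted p = 0.0621). The list had adjusted p = 0.0029 by camera, lower in HTB, and adjusted p = 0.55 with an estimated correlation. In the fit without HTB replicate 2, 8 members fell. Among 20 unfolded protein response genes Sdf2l1 (-0.46 ± 0.10) and Calr (-0.29 ± 0.08) fell in both counts, and Hsp90b1 stood at -0.24 ± 0.08 (adjusted p = 0.094), with adjusted p = 0.0063 by camera and adjusted p = 0.259 with an estimated correlation. With HTB replicate 2 left out, 5 of the 20 fell.

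The lists of TGF-beta and mesenchymal transition genes, of immediate early and stress genes, and of oxidative phosphorylation genes did not pass camera (adjusted p = 0.911, 0.333 and 0.882). In the TGF-beta list Tgfb1 (-0.49 ± 0.08) and Smad7 (-0.38 ± 0.11) fell and Snai1 (0.56 ± 0.14) rose among 20 members, or 3 and 1 adjusted over the list alone; without HTB replicate 2, 3 fell and 3 rose. In the immediate early list Egr3 (0.42 ± 0.10) rose and Atf3 (-0.95 ± 0.24), Hsp90aa1 (-0.48 ± 0.13) and Dnajb1 (-0.29) fell among 24 members, or 3 and 3 adjusted over the list alone. In the fit without HTB replicate 2, 2 of the 24 rose and 7 fell. That list's median was -0.01 and its mean 0.14. None of 30 oxidative phosphorylation genes passed edgeR's test, over all genes or over the list alone, while 2 had an unadjusted p under 0.05 and DESeq2 called 0 of the 30. Ndufa4, Cox5a and Sdha stood at 0.47 ± 0.18, -0.48 ± 0.20 and 0.19 ± 0.10. Without HTB replicate 2, 4 of these 30 genes fell and the list was lower in HTB with adjusted p = 0.0383 by camera, and adjusted p = 0.539 with an estimated correlation.

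Markers of stroma and neighbouring tissues were examined in the same way. Of 26 fibroblast and matrix genes, Fbn1 (-0.73 ± 0.19), Thy1 (-1.10 ± 0.30) and Col6a3 (-0.47 ± 0.13) fell, also 3 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.818). With HTB replicate 2 left out, 4 of the 26 rose and 4 fell. Its median was 0.20, while the list mean per library, HTB minus LTB, was -0.12 on the log2(CPM + 1) scale. Erythroid genes rose in 5 of 6 members in both counts, including the haemoglobin genes Hba-a1 (2.27 ± 0.53; 42.2 ± 43.0 against 8.71 ± 2.34 CPM, SD, n = 5 each), Hbb-bs (2.01 ± 0.50) and Hbb-bt (2.15 ± 0.57). Hbb-bs and Hbb-bt are near-identical, as are Hba-a1 and Hba-a2, so reads could be split within each pair. Hba-a1, Hbb-bs and Hbb-bt rose by 1.40, 1.19 and 1.30 without HTB replicate 2. The list had adjusted p = 0.0011 by camera and adjusted p = 0.183 with an estimated correlation, and without HTB replicate 2 the same number, 5, passed with a list median of 1.24 in place of 2.11.

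Of 12 skeletal muscle genes, Acta1, Tnnt3 and Atp2a1 rose, or 9 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0618). It passed, higher in HTB, with the replicate number as a block (adjusted p = 0.0334) and with no filter on low counts (adjusted p = 0.0018, 22 members). It also passed without HTB replicate 1, 4 or 5 and without LTB replicate 1, 2, 3 or 4 (adjusted p between 0.0055 and 0.0438). All of these fits include HTB replicate 2, without which the adjusted p was 0.268, and it was 0.629 with an estimated correlation. In the fit without HTB replicate 2, 2 of the 12 rose and 1 fell. Its mean per library was 8.44 in HTB replicate 2, 1.41 to 2.98 in the other HTB libraries and 1.37 to 1.71 in LTB. None of 6 adipocyte genes passed edgeR's test over all genes, 2 rose adjusted over the list alone, 4 had an unadjusted p under 0.05 and DESeq2 called 1 of the 17 it tested. Plin4, Fabp4 and Lipe stood at 1.12 ± 0.34, 4.52 ± 1.46 and 2.34 ± 0.95 (adjusted p = 0.0554, 0.0705 and 0.132), and Fabp4, a fatty acid carrier of fat cells, had 1924 CPM in HTB replicate 2 and 24.2 CPM or less elsewhere. Without that library Plin4, Fabp4 and Lipe stood at 0.84, 0.36 and -0.0029 (adjusted p = 0.0584, 0.224 and 0.99). The list did not pass camera (adjusted p = 0.169), and without HTB replicate 2, 1 of the 6 genes fell.

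None of 17 endothelial genes passed edgeR's test in either count, 5 had an unadjusted p under 0.05 and DESeq2 called 2. Tek, Erg and Sox18 stood at 1.80 ± 0.56, 0.96 ± 0.33 and 1.29 ± 0.49 (adjusted p = 0.0628, 0.0844 and 0.112). Without HTB replicate 2 they stood at 0.88, 0.55 and 0.46 (adjusted p = 0.0369, 0.0676 and 0.0894), so that Tek passed there, and of the 17 genes 1 rose and 2 fell. Camera placed the list higher in HTB with adjusted p = 0.0344, and adjusted p = 0.629 with an estimated correlation. Without HTB replicate 2 the preset value was 0.531, and without LTB replicate 5 it was 0.104. Of 5 tested epithelial genes, Cdh1 (-1.36 ± 0.35) fell and Lgals4 and Epcam stood at 0.53 ± 0.19 (adjusted p = 0.0888) and -0.89 ± 0.54 (adjusted p = 0.295), with 1 rising and 1 falling adjusted over the list alone and adjusted p = 0.274 by camera. With HTB replicate 2 left out, 1 of these 5 genes rose and 1 fell. Of 3 tested keratinocyte genes, the basal keratin gene Krt14 fell (-3.19 ± 0.53; 4.38 ± 3.54 against 39.9 ± 9.51 CPM, SD, n = 5 each; adjusted p = 0.0057), also the 1 call adjusted over the list alone. Sfn and Krt10 stood at 0.055 ± 0.12 and -0.0029 ± 0.17, and the list did not pass camera (adjusted p = 0.298). It passed, lower in HTB, with no filter on low counts (adjusted p = 0.0076, 19 members) and by fry (adjusted p = 0.0012), which tests against no change and rests on Krt14. With the 3 tested members it had adjusted p = 0.468 with an estimated correlation.

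**Figure D4:**
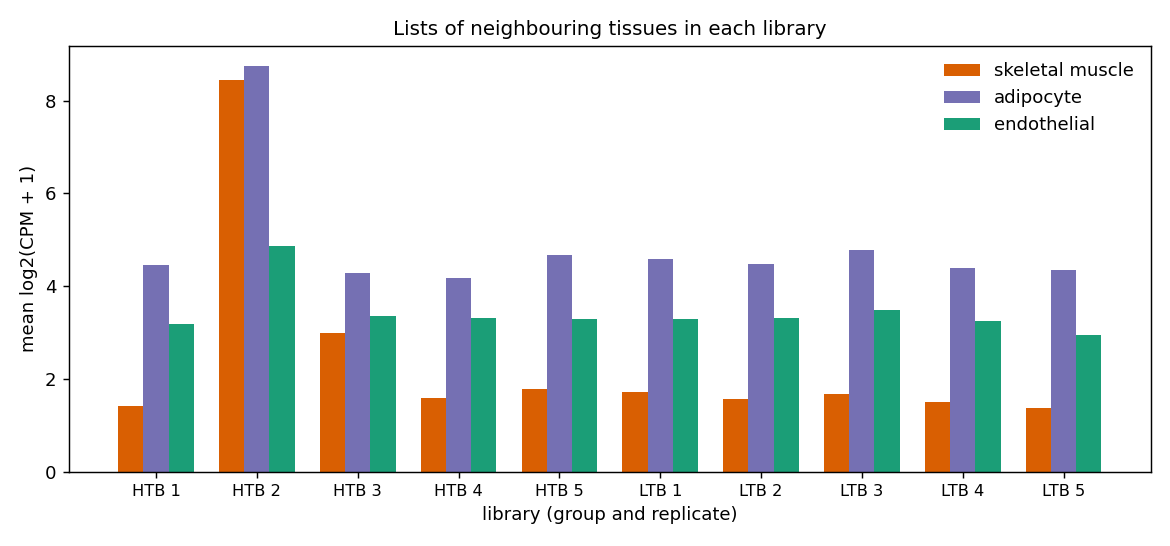
Mean log2(CPM + 1) of the tested skeletal muscle, adipocyte and endothelial genes in each of the 10 libraries. HTB replicate 2 stands at 8.44, 8.75 and 4.88, and no other library exceeds 2.98, 4.78 and 3.48.

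With the preset correlation, camera placed 16 of 28 lists lower and 3 higher in HTB. The same setting also called 4 to 22 lists in splits that mixed the groups, as described in the closing section. Its small p-values are therefore no measure of certainty. With a correlation estimated for each list, 0 passed by camera, with a smallest adjusted p of 0.145 and 7 lists at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 15 lower and 2 higher. Fry did not call the macrophage, neutrophil, proliferation and endothelial lists (adjusted p = 0.123, 0.126, 0.201 and 0.394).

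A second test kept the correlation of genes within a library by comparing 1 mean per list and library. By the exact two-sided permutation test over all 252 arrangements of 5 against 5, 15 lists had a lower and 1 a higher mean in HTB, the erythroid list. The antigen presentation mean was 6.37 ± 0.36 in HTB and 7.98 ± 0.19 in LTB (SD, n = 5 each; exact permutation p = 0.0079, adjusted p = 0.0159), and the T cell mean 1.93 ± 0.34 and 3.25 ± 0.64 (exact permutation p = 0.0079, adjusted p = 0.0159). The value 0.0079 is the smallest these arrangements can give. The lists that passed were those of antigen presentation, interferon, chemokines, T cells, cytotoxic cells, regulatory T cells, checkpoints, alternatively activated and inflammatory macrophages, dendritic cells, B and plasma cells, hypoxia and glycolysis, keratinocytes, STAT3 and unfolded protein response, all lower in HTB, and the erythroid list. The unfolded protein response list passed by little (exact permutation adjusted p = 0.0417). It lost its call without HTB replicate 2 (exact permutation adjusted p = 0.0833) and in 7 of the other 9 tests without 1 library. Of the 3 keratinocyte genes Krt14 alone passed edgeR's test. The general macrophage list did not pass (5.55 ± 0.28 against 5.96 ± 0.39, exact permutation p = 0.0794, adjusted p = 0.122), nor did the neutrophil list (1.73 ± 0.54 against 2.65 ± 1.0, exact permutation p = 0.0873, adjusted p = 0.122).

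The series title names IGFBP2, STAT3 and PD-L1 as a pathway of macrophages, so relations among Igfbp2, Stat3, Cd274 and the macrophage list were planned across libraries. Igfbp2, Stat3 and Cd274 each separated the 5 HTB from the 5 LTB libraries with no overlap. The gap was narrow for Stat3, with a highest HTB value of 6.87 and a lowest LTB value of 6.92 on the log2(CPM + 1) scale. For Igfbp2 it was 0 reads against 1. A correlation over both groups would restate the group difference, so none is given. Of the 4 planned relations, the 3 with Igfbp2 were not computed within groups, because Igfbp2 was 0 in all HTB libraries and only the 5 LTB libraries vary. Stat3 with Cd274 was tested within groups on log2(CPM + 1) centred per group, as 1 test, so adjustment leaves p unchanged. Over the 10 libraries Pearson's r was 0.62 (exact permutation within groups, p = 0.0553) and Spearman's rho, on ranks within groups, 0.45 (exact permutation p = 0.246), and neither passed. Without the 2 libraries farthest from the median of Stat3, LTB replicate 1 and HTB replicate 2, r was 0.723 (exact permutation p = 0.0938). Without LTB replicate 1 alone r was 0.286 (exact permutation p = 0.499), and without HTB replicate 2 alone it was 0.854 (exact permutation p = 0.0076), with rho 0.667 (exact permutation p = 0.103). A relation within groups is therefore open.

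The most abundant genes took similar shares of the reads in both groups. The 50 most abundant genes held 11.7 ± 0.27% of reads in HTB and 12.1 ± 0.50% in LTB (SD, n = 5 each), a difference that did not pass the exact two-sided permutation test (p = 0.222). Total reads per library, 26567670 ± 972330 in HTB and 25116552 ± 1890010 in LTB, did not pass it either (exact permutation p = 0.19).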

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

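Both tests of the muscle and fat transcripts were chosen after those values had been seen. Each value below is a library that lay far from the other 4 of its group, with a gap to its nearest neighbour above 0.71 of the group's range. Chance alone does this in about 1 of 20 groups, and 35 of the 246 groups of values tested did so, 21 of them through HTB replicate 2 and 6 through LTB replicate 1. Values are log2(CPM + 1), or means of it over a list.

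HTB replicate 2 was the highest HTB library in the means of the skeletal muscle (8.44, others 1.41 to 2.98), adipocyte (8.75, others 4.17 to 4.67), endothelial (4.88, others 3.17 to 3.35), erythroid (4.34, others 2.48 to 2.88), insulin-like growth factor (6.91), TGF-beta (6.13) and oxidative phosphorylation lists (7.08). The same library stood apart in the muscle genes Atp2a1 (10.81) and Tnnt3 (10.67), the fat genes Fabp4 (10.91) and Lipe (7.66), the endothelial genes Tek (3.94), Erg (3.61) and Sox18 (4.96) and the haemoglobin genes Hba-a1 (6.90), Hbb-bs (6.48) and Hbb-bt (3.78). It also did so in Ablim3 (4.02), Slco2b1 (4.88) and Sdha (8.03), and it had the lowest total of its group, 24884292 reads against 26571133 to 27185168.

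The muscle and fat transcripts of this library may come from tissue next to the tumour. All of the tested genes of the skeletal muscle and adipocyte lists, 18 of 18 or 100%, were highest in this library, where their median was 9.28 against 3.05 in the next library. Tumour burden as the source was examined through the other 4 HTB libraries. Without replicate 2 the median log2 fold change of these genes was 0.48, with quartiles of -0.31 and 1.13, so a smaller rise with burden stays open. Among the other HTB libraries, replicate 3 had the highest muscle list mean, 2.98 against 1.41 to 1.78, so a rise without replicate 2 may rest partly on replicate 3. Without replicate 2 Acta1 and Tnnt3 rose, while 1 other muscle gene and 1 fat gene fell.

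LTB replicate 1 was the highest LTB library in the means of the neutrophil (4.39, others 1.87 to 2.50) and chemokine lists (5.15, others 4.25 to 4.51), and in the genes Msr1 (7.36), Tnfrsf4 (3.45), Acod1 (6.996) and Tgfb1 (6.90).

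Of the other 8 values, HTB replicate 5 was lowest in the macrophage list (5.04, others 5.64 to 5.72) and in Foxp3 (0.24, others 0.70 to 0.79). HTB replicate 4 was highest in the neutrophil list (2.66), F10 (2.16) and Atf3 (4.13). HTB replicate 1 was highest in Mcpt2 (0.52, others 0 to 0.05) and Ccr8 (0.10), and LTB replicate 2 was highest in Irs1 (6.01, others 5.64 to 5.73). Mcpt2 and Ccr8 were near the detection limit in HTB, so few reads decide their flags.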

How the results depend on the processing

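Thinning of the libraries and leaving out HTB replicate 2 together with LTB replicate 1 were chosen after the data had been seen. No gene that passed in the main test and in an alternative changed sign between them. The cause was not tested for any difference below, except where the setting itself uses fewer libraries or another threshold. Of 1537 genes, 526 higher and 1011 lower in HTB, the count became 2526 by the DESeq2 Wald test (1097 higher), 3592 by voom with sample quality weights (1605 higher, 1987 lower) and 2907 without HTB replicate 2 and LTB replicate 1 (1245 higher, 1662 lower). By threshold it was 2624 at 0.1 (1131 higher), 388 at 0.01 (58 higher, 330 lower) and 609 with at least 2-fold (63 higher, 546 lower). Leaving out 1 library gave 739 to 3040 genes, 177 to 1324 higher and 561 to 1716 lower. The other scalings, filters, voom and thinning gave 1274 to 1567. At these depths a simulated 1.5-fold change was called in 34% of changed genes, all with a mean above 1 CPM.

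Libraries of the same replicate number correlated weakly (0.0016 to 0.109). Replicates 4 and 5, at 0.109 and 0.107, lay just above the minimum of 0.1 set for a pair, so a shared factor is not excluded. With the replicate number as a block the counts were 971 genes, 221 of them higher. The exact sign-flip permutation test within replicate numbers cannot go below p = 0.0625, so its 0 lists by list mean say nothing on stability. Its exact p for the share of the 50 most abundant genes was 0.25. For Stat3 with Cd274 within groups, which did not pass, leaving out 1 library gave r of 0.286 to 0.854, and it passed without HTB replicate 2 alone (r = 0.854, exact permutation p = 0.0076).

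With an estimated correlation 0 lists passed camera, 0 lower and 0 higher. The lists higher in HTB, 3 in the main test, numbered 1 without HTB replicate 2 and LTB replicate 1, and 1 to 4 when 1 library was left out. Of 93 named genes 74 passed in the main test. Calls were lost by 22 without HTB replicate 3, by 18 without LTB replicate 1, by 18 without LTB replicate 4, by 17 without LTB replicate 3, by 16 each without HTB replicate 4, without LTB replicate 5 and with the block, and by 13 or fewer in every other setting. Direction changed only in lists and genes that had not passed in the main test. Without both libraries this held for the fibroblast (adjusted p = 0.698), adipocyte (0.765), TGF-beta (0.624) and oxidative phosphorylation lists (0.188), for the means of the adipocyte (-0.106) and oxidative phosphorylation lists (-0.0568), and for Lipe (-0.10) and Krt10 (0.048). Fry turned the TGF-beta list (adjusted p = 0.816), and z-scores the means of the fibroblast (0.0678) and TGF-beta lists (0.0162). Krt10 was 5.35e-04 with DESeq2 size factors, 0.035 by voom with weights, 0.0093 without a filter and 0.0041 with the block. Leaving out 1 library, camera's adjusted p ranged from 0.444 to 0.968 for the fibroblast, 0.0509 to 0.956 for the adipocyte, 0.709 to 0.956 for the TGF-beta and 0.0383 to 0.916 for the oxidative phosphorylation list. The means ranged from -0.124 to 1.02 for the adipocyte, -0.184 to 0.0079 for the immediate early and -0.0993 to 0.0432 for the oxidative phosphorylation list. Log2 changes ranged from -0.0107 to 0.116 for Sfn, -0.0845 to 0.0655 for Krt10 and -0.0029 to 2.61 for Lipe.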

Other observations

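Tests chosen after the result was seen are those of tissue admixture, of fewer host cells and of exchanged labels, and the lists of mast cell, resident macrophage and glucocorticoid genes, like the division of the interferon list, were drawn up after the genes that prompted them had been seen. The remaining mast cell genes named here were chosen after their values were seen. Mast cell protease genes were lower in HTB beyond Mcpt2: Tpsb2 changed by -3.35 ± 0.65 (log2, SE; adjusted p = 0.0107, edgeR quasi-likelihood test), Cma1 by -3.26 ± 0.69 (adjusted p = 0.0155), Cpa3 by -3.22 ± 0.56 (adjusted p = 0.007) and Mcpt4 by -3.07 ± 0.67 (adjusted p = 0.0174). Of 9 other mast cell genes, Fcer1a (-2.72 ± 0.69), the high-affinity IgE receptor, and Mrgprb1 (-2.60 ± 0.58) fell and 0 rose, and without HTB replicate 2 Kit and Il1rl1 fell too, 4 of the 9. Fewer mast cells may account for this, but the 9 genes gave a camera p of 0.0525 (0.141 with an estimated correlation, 0.047 without HTB replicate 2), on either side of the threshold, so the hypothesis stays open.

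The interferon list divides into genes that lean to interferon gamma and genes that lean to interferon alpha. All 14 tested gamma-leaning genes fell (median -1.76), with Gbp4 at -2.99 ± 0.37 and Igtp at -2.16 ± 0.23, while 4 of 16 alpha-leaning genes fell (median -0.48), with Bst2 at -1.03 ± 0.21 and Ifit1 at -0.10 ± 0.35 (adjusted p = 0.869). The prediction that the gamma-leaning mean falls more was met: the difference of the 2 means was lower in HTB by -1.37 on the log2(CPM + 1) scale (exact permutation p = 0.0079, the smallest possible), and by -1.52 without HTB replicate 2 (exact permutation p = 0.0079). A lower interferon gamma signal in HTB tumours is a candidate explanation, in which Ifng itself also fell, by -2.83 and, without LTB replicate 1, by -2.11.

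The lower immune, interferon and antigen presentation genes in HTB were weighed against 3 explanations. Tissue admixture in HTB replicate 2 is argued against. Without that library, 100% of the 64 called genes of the T cell, cytotoxic, interferon and antigen presentation lists still passed. Sequencing depth leaves little room as an explanation, since library totals differed little, at 23070917 to 27185168 reads. With all libraries thinned to the smallest total, 100% of the 64 passed too. That thinning removed few reads, so it could hardly change these calls. A lower share of every kind of host cell is argued against by the T cell mean, which fell relative to the endothelial mean. That difference was -1.67, and -1.39 without HTB replicate 2 (exact permutation p = 0.0079 for both). Relative to the fibroblast mean it was -1.21 (exact permutation p = 0.0079), and -1.12 without HTB replicate 2 (exact permutation p = 0.0159). Whole tumours do not show whether tumour cells also made the fibroblast and matrix genes, so this contrast is the weaker one. What stays open is whether fewer immune cells or lower expression per cell lies behind the pattern, which whole-tumour libraries do not separate.

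Igfbp2, Stat3 and Cd274 were lower in HTB, although the series title links this pathway to high burden. An exchange of 1 library between the groups is argued against, since 0 libraries had a Cd274 value inside the range of the other group. An exchange of the labels of all 10 libraries cannot be told apart from a true fall, because 0 samples carry a label with a measured tumour size. Hypoxia and glycolysis genes, 17 of 27 of which fell in HTB, do not settle it either. The title speaks of macrophages, and whole tumours do not show the level in 1 cell type, so a biological difference stays open and untested.

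Of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave as many genes as the real 1537. The highest other split gave 2. This argues against chance for that count but, with 100 splits, does not exclude it. It also does not tell burden from any other difference between the groups. For the number of lists passed by camera with the preset correlation, 14 of the 100 splits gave at least the real 19, and the highest other gave 23. The splits that gave 23 kept 4 HTB libraries together, so they retain much of the real contrast and are no pure chance groups. Splits with 2 or 3 HTB libraries on each side, which mix the groups most, gave 4 to 22 lists. Camera at this setting thus called lists in mixed groups too, and chance is not excluded for the number of lists.

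Lyve1, Cd163 and Slco2b1, which rose in HTB, are expressed by resident tissue macrophages, and more of these cells was tested as a hypothesis. The 12 other resident macrophage genes gave a camera p of 0.806 and a median of 0.06, with quartiles of -0.36 and 0.78. The 3 genes were picked for their large rises, so their size is no measure for the other 12. Selenop (0.83 ± 0.19) rose, and Mgl2 (-3.04 ± 0.80) and Ccl8 (-1.73 ± 0.45) fell. The predicted joint rise of the 12 genes was not seen, but so few genes cannot exclude a smaller increase of these cells.

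Per2 (1.66 ± 0.24, adjusted p = 0.0033), a clock gene, and Depp1 (1.70 ± 0.29, adjusted p = 0.0066) rose in HTB, and Per2 is known to respond to glucocorticoids. Of 14 other glucocorticoid-induced genes Fkbp5 (0.50 ± 0.11), Tsc22d3 (0.61 ± 0.14) and Errfi1 (0.84 ± 0.11) rose and 0 fell. Without HTB replicate 2, 4 rose and 2 fell, Mt1 (-0.73, adjusted p = 0.0386) and Mt2 (-0.71, adjusted p = 0.0396). A glucocorticoid response may be involved, but the camera p of 0.021 became 0.156 with an estimated correlation and 0.0497 without HTB replicate 2, so it stays open.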
